A study of Mus musculus with 15 samples.

How the data were processed

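The authors deposited 1 table per library with an Ensembl gene identifier and a value that the labels give as TPM, and the deposited values were used as TPM. Values were not negative, were not whole numbers, and summed to between 819697 and 938139 per library. TPM keep no read depth, so the depth of the libraries is unknown and no count model was fitted. The authors' processing notes name STAR, Salmon and DESeq2 and the mm10 genome; versions, and the role of each tool, are not given in the sources used here. All 15 libraries were used, with groups taken from the labels: unstimulated WT (n = 4), unstimulated KO (n = 6), WT with beads (n = 3) and KO with beads (n = 2). Library names follow the number in each title, and the 2 libraries without a number, 1 WT and 1 KO, are called unnumbered.

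The 10 unstimulated tables list 36904 genes, and 31785 genes are listed in the 5 bead tables, each gene above 0 in at least 2 libraries of its set. The analysis used the 30949 genes in both, 30788 of them with a symbol in GENCODE vM21 on GRCm38 (mm10), which also gave the coordinates; 5955 genes listed for unstimulated and 836 listed for bead libraries alone were left out of the tests. No mitochondrially encoded gene is listed. Genes with at least 1 TPM in at least 2 libraries were kept, 29989 in all. log2(TPM + 1) was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over 15 libraries (11 residual degrees of freedom) and the trend option for the variance. Each of the 5 comparisons was a contrast of group means, adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Every adjusted p for a single gene is from this fit, or from the same fit under the alternative named beside it. log2 differences are on the log2(TPM + 1) scale and SE are from limma, while ± beside TPM is the SD between libraries.

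Gene lists were written from general knowledge before the files were opened: 38 lists with 925 genes, of which 894 were found and 881 tested, and 37 lists kept at least 5 tested members. Lists were tested with camera at its preset correlation of 0.01, again with a correlation estimated for each list, and with fry, each adjusted over the 37 lists. Members were counted as called over all genes, and again with the adjustment over the list alone. Dock8 and library measures were compared with exact two-sided permutation tests over every assignment of libraries to groups, 210 without beads and 10 with beads, so that the smallest possible p was 0.00476 and 0.1. Agreement between comparisons was measured by correlations of log2 changes and by overlaps set against independent lists.

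The genes named in the text followed a rule written before the data were examined. Dock8, Foxp3, Il2ra, Il2rb, Ctla4 and Entpd1 were always given. For each comparison up to 8 called genes in each direction with the largest change were added, 4 for the difference between bead responses, from genes with a mean of at least 5 TPM in the higher group and no overlap between groups, leaving out predicted genes, RIKEN clones, microRNAs, pseudogenes and antigen receptor segments. For each list described, up to 4 called members with the smallest p were eligible, or 2 members where none was called. A gene or library measure named outside this rule was chosen after its values were seen. Some genes that the rule would allow are not reported here.

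The main fit, the comparisons, the gene lists and these alternatives were chosen before the data were examined: pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-ratio scaling over 9402 genes, quantile normalization, values rescaled without ribosomal genes, only the groups compared, array weights, the title number as a block, no unnumbered libraries, and each library left out in turn. After the data were seen 6 alternatives were added: scaling to 804 abundant genes with a mean of at least 50 TPM in every group; leaving out 11 repeat-derived predicted genes; testing the 5937 genes with a mean of at least 20 TPM in at least 1 group; both that set and that scaling; the log2 mean of 1241 receptor, keratin-associated and defensin genes that T cells do not use as a covariate; and leaving out the 4 unstimulated KO libraries with more than 35% of TPM in repeat-derived genes. Lists were tested in the abundant genes where at least 5 members were among them, and called members there were counted in the same way.

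A self-test drew values from the fitted model with no differences and then changed 200 of the 29989 genes, taken from those with a mean of at least 20 TPM, by 1, 2 or 3 on the log2 scale. Changes of 2 were called in 77.6% of genes for KO against WT without beads, 41.8% with beads, 59.7% for beads in WT, 50.7% for beads in KO and 2.99% for the difference between responses, and changes of 1 in 8.96%, 0%, 5.97%, 1.49% and 0%. False calls numbered 13, 5, 8, 10 and 1. A list of 40 genes shifted by -1 was called in all 5 comparisons, beside 3, 1, 3, 1 and 0 of the 36 other lists. Genes were drawn independently of each other, so the list test was checked only where genes are not correlated. Each gene was drawn with the same spread in all groups, while in the data bead libraries correlated more closely than unstimulated ones. The shares called therefore hold for groups of equal spread. Random draws were made in R 4.3.3, and figures used numpy 2.4.6 and matplotlib 3.10.9.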

Results

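Regulatory T (Treg) cells, the T cells that hold other immune cells in check, were sorted from spleen and lymph nodes of female C57BL/6 mice. The mice had floxed Dock8 and a YFP-Cre fusion in the Foxp3 gene of 1 X chromosome. Because each female cell silences 1 X chromosome, such mice carry Treg cells with Cre (YFP+, DOCK8 deficient, called KO here) beside Treg cells without it (YFP-, called WT). CD25+CD39+ cells, sorted as CD3+ in the growth protocol and as CD4+ in the design, were cultured for 16 h in medium alone or with anti-CD3 and anti-CD28 beads, at 1 bead per cell, which engage the T cell receptor and its costimulator CD28. Smart-Seq2, which copies polyadenylated transcripts from small numbers of cells, was run on 15 samples: 4 WT and 6 KO without beads, 3 WT and 2 KO with beads. The series title concerns IL-2 signalling and the immune synapse. The comparisons asked how the transcriptome differed with DOCK8 deficiency at rest and after T cell receptor stimulation, and whether the bead response differed between genotypes. The KO cells were also the cells that carried YFP and Cre. The labels call the samples independent without saying whether mice or cultures were separate, so that p-values measure the spread between these samples.

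Values were deposited as TPM, a transcript's share of its library, which keeps no read depth, so the depth behind each value is unknown. Each unstimulated library listed 36904 genes and each bead library 31785, with TPM summing to between 819697 and 938139. Correlation across genes, which are not independent replicates, was 0.766 to 0.830 between unstimulated WT libraries, 0.706 to 0.784 between unstimulated KO libraries. It was 0.895 to 0.903 between WT bead libraries and 0.874 between the KO bead libraries. A set of 11 predicted genes made of repeats, such as Gm10800, took 25.4 ± 7.41% of TPM in unstimulated WT (SD, n = 4) and 36.1 ± 8.18% in unstimulated KO (n = 6; exact permutation p = 0.0714). With beads the shares were 11.6 ± 2.82% and 15.1 ± 3.77% (n = 3 and 2; exact permutation p = 0.4). A scale factor from 804 abundant genes was 1.09 ± 0.156 in unstimulated WT and 0.840 ± 0.169 in unstimulated KO libraries (n = 4 and 6; exact two-sided permutation p = 0.0476). Genes with a mean of at least 20 TPM in a group, 5937 in all, had a median log2 difference of -0.44 between unstimulated KO and WT as deposited and -0.08 after scaling to the abundant genes. The median of all genes tested moved from -0.11 to 0.13 with that scaling. It moved from -0.23 to -0.47 for the bead response in KO cells and from 0.27 to -0.06 for the difference between bead responses. Values scaled in this way are called scaled below.

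Dock8 (ENSMUSG00000052085, chromosome 19, 24999534 to 25202432, plus strand, mm10) encodes a guanine nucleotide exchange factor that activates Cdc42 and organises actin in lymphocytes. It was read at 14.6 ± 5.35 TPM in unstimulated WT (SD, n = 4) and 8.58 ± 1.85 TPM in unstimulated KO cells (n = 6). The difference was -0.67 on the log2(TPM + 1) scale (exact two-sided permutation p = 0.0190, n = 4 and 6), and 4 of the 6 KO libraries lay below every WT library. With beads, WT cells had 9.25 ± 0.763 TPM (n = 3), and both KO libraries were lower, at 7.90 and 5.82 TPM. The log2 difference of -0.39 had an exact permutation p of 0.1, the smallest that 3 against 2 samples allow. The unstimulated difference was no longer past the threshold when scaled (-0.31, exact permutation p = 0.138) or without WT library 3 (-0.46, exact permutation p = 0.0714). A TPM value sums over the whole gene, so a transcript from a recombined allele still counts as Dock8 here. The exons removed by Cre are not given in the sources used here.

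**Figure D1:**
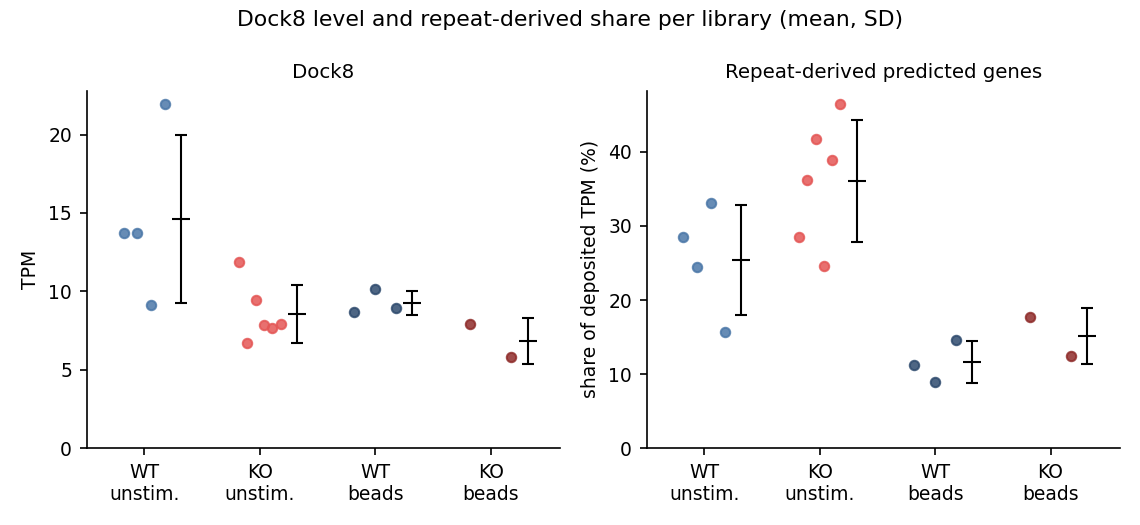
Dock8 in TPM and the share of TPM in 11 repeat-derived predicted genes in percent (y axes) in each library of the 4 groups (x axis); points are libraries and bars are the mean with SD. Dock8 averaged 14.6 TPM in unstimulated WT and 8.58 TPM in unstimulated KO cells, and the repeat-derived share averaged 25.4% and 36.1% in the same groups.

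Without beads, Tigit, Pdcd1, Cxcr6 and Klrg1 were called lower in DOCK8-deficient Treg cells. Tigit, a coinhibitory receptor, fell by 1.99 on the log2 scale (SE 0.22, limma adjusted p = 0.00218), from 197 ± 29.9 TPM in WT (SD, n = 4) to 49.3 ± 9.65 TPM in KO (n = 6). Pdcd1, which encodes PD-1, fell by 3.16 (SE 0.43, limma adjusted p = 0.0185), from 63.7 ± 26.4 to 6.98 ± 5.24 TPM. Cxcr6, a chemokine receptor of tissue-homing T cells, fell by 3.18 (SE 0.42, limma adjusted p = 0.0160), from 29.9 ± 11.9 to 2.54 ± 1.57 TPM. Klrg1, a receptor of late effector cells, was read at 4.57, 9.70, 2.80 and 16.1 TPM in WT cells and was listed at 0 in 5 KO libraries and at 0.978 TPM in the unnumbered one (limma adjusted p = 0.0239).

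limma called 22 of 29989 genes between unstimulated KO and WT cells, 20 lower and 2 higher in KO. An unadjusted p under 0.05 was reached by 3386 genes, of which 2666 were lower, against 1499 expected by chance. The fit shared its spread with the bead libraries, which correlated more closely with each other, so this count may be too high. Cxcr3, the chemokine receptor that draws T cells to sites of type 1 inflammation, was at 24.3, 14.2, 15.3 and 25.6 TPM in WT (limma adjusted p = 0.0331). In 5 KO libraries it was at 4.95, 0.993, 1.24, 3.83 and 0.361 TPM, and it was listed at 0 in the other. Id2, an inhibitor of E proteins, fell by 2.08 (SE 0.36, limma adjusted p = 0.0487), from 23.7 ± 13.1 to 4.57 ± 1.99 TPM. Acot7, a thioesterase that cleaves fatty acyl-CoA, fell from 31.5 ± 8.64 to 5.67 ± 3.46 TPM and Ptpn4, a protein tyrosine phosphatase, from 13.7 ± 9.92 to 1.33 ± 0.868 TPM (limma adjusted p = 0.0487 and 0.0399). Ccdc40, a coiled-coil protein of cilia, was between 4.69 and 24.4 TPM in WT and at most 3.29 TPM in KO cells, with 1 KO library at 0 (limma adjusted p = 0.0487). Samt4, a gene of the X chromosome, was higher (limma adjusted p = 0.0331), listed at 0 in all WT libraries and with at least 1.61 TPM in each KO library.

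Genes at the centre of Treg identity did not pass the threshold. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand), the transcription factor that defines the lineage, was at 43.2 ± 10.4 TPM in WT and 13.3 ± 6.77 TPM in KO (log2 -1.71, SE 0.31, limma adjusted p = 0.0646), with every KO library below every WT library. KO cells read Foxp3 from the allele with the YFP-Cre fusion, and WT cells from the other. Cxcr3 and Samt4, above, also lie on the X chromosome. For these genes, with or without beads, an effect of the X chromosome in use cannot be told apart from DOCK8 deficiency. Without the unnumbered KO library Foxp3 was called (log2 -1.92, limma adjusted p = 0.00990, range 0.00990 to 0.384 over its alternatives). Ctla4, Tnfrsf18 and Stat4, below, and Hcls1 and Atp5c1, in later paragraphs, were called without that library as well (limma adjusted p = 0.0176, 0.0495, 0.0489, 0.0371 and 0.0348). Ctla4, which removes costimulatory ligands, was at 52.4 to 95.9 TPM in WT and 19.9 to 51.6 TPM in KO (limma adjusted p = 0.123). Il2rb, the beta chain of the IL-2 receptor, was at 55.1 ± 27.6 and 23.9 ± 13.5 TPM (limma adjusted p = 0.242). The genes behind the sort were closer in level as deposited. Il2ra, which encodes CD25, was at 11.3 ± 3.90 and 11.2 ± 4.43 TPM (limma adjusted p = 0.981). Entpd1, which encodes the ectonucleotidase CD39, was at 181 ± 33.5 and 229 ± 63.2 TPM (limma adjusted p = 0.689). When scaled, the log2 differences were 0.32 for Il2ra and 0.71 for Entpd1, beside -0.84 for Il2rb and -0.90 for Ctla4. The transcription factor Stat4, which transmits IL-12 signals, was at 43.6 ± 13.2 and 13.2 ± 4.88 TPM (limma adjusted p = 0.0724). Tnfrsf18, which encodes the costimulatory receptor GITR, was at 130 ± 42.0 and 52.8 ± 15.7 TPM (limma adjusted p = 0.0998).

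**Figure D2:**
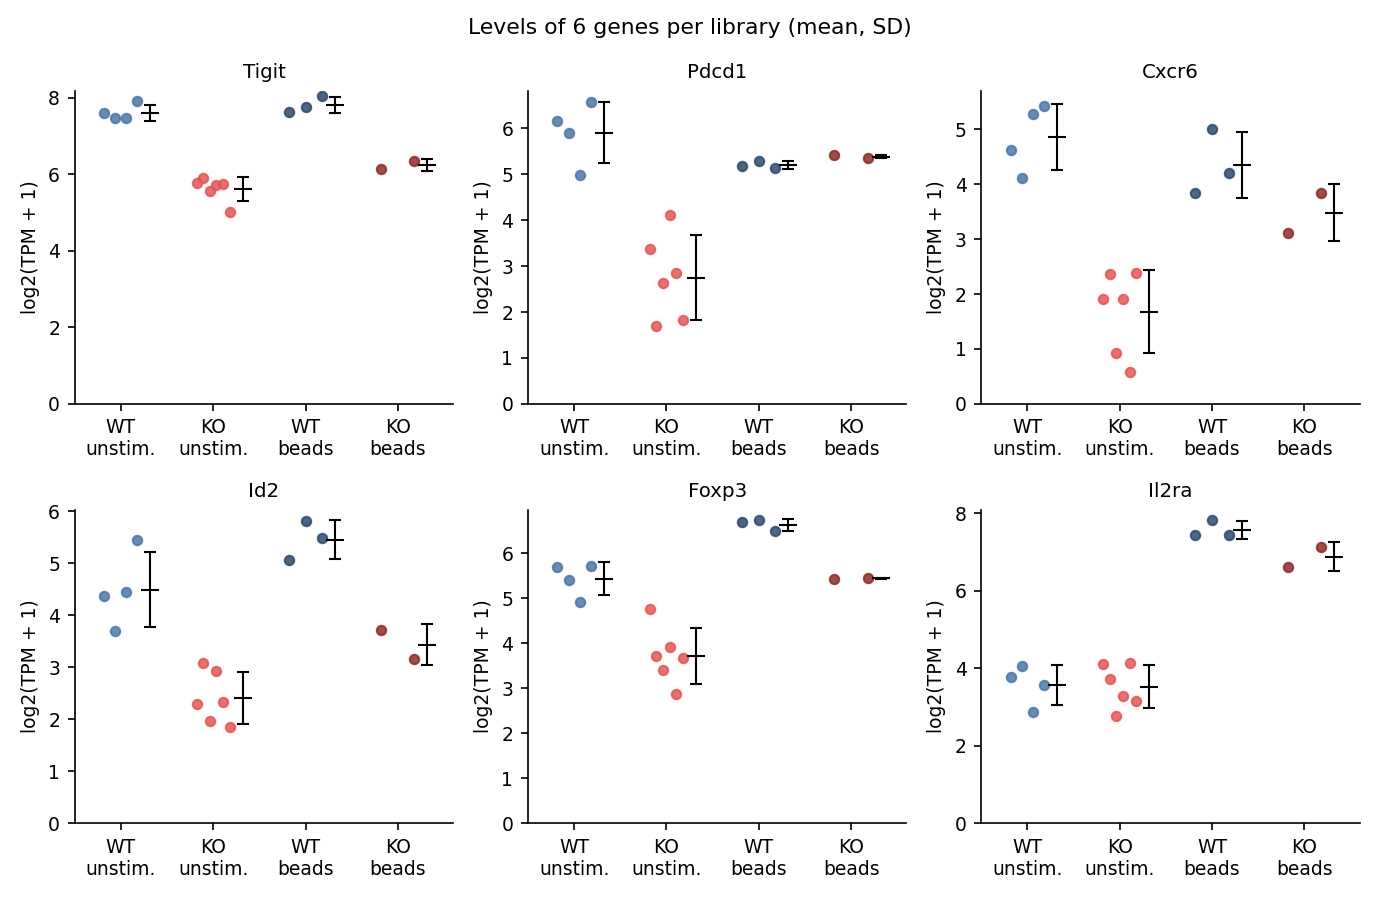
Expression of Tigit, Pdcd1, Cxcr6, Id2, Foxp3 and Il2ra as log2(TPM + 1) (y axes) in each library of the 4 groups (x axis); points are libraries and bars are the mean with SD. Tigit lay between 176 and 239 TPM in unstimulated WT and between 31.5 and 59.4 TPM in unstimulated KO libraries, while Il2ra averaged 11.3 and 11.2 TPM there.

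Gene lists fixed in advance were lower in unstimulated KO cells more often than higher. camera with its preset correlation called 20 of 37 lists, 19 lower and 1 higher. With an estimated correlation it called 0, and fry called 17. camera compares a list with the other genes tested, and the median over all genes tested was -0.11. All 5937 abundant genes had a median of -0.44, so a list median near -0.44 does not set a list apart from abundant genes in general. Among abundant genes and when scaled, camera with its preset correlation called 10 of 27 lists, all lower. Effector Treg genes had a median log2 difference of -1.22 over 40 members (camera adjusted p = 3.86e-20; adjusted p = 0.0534 with an estimated correlation). Among all genes 5 members were called lower, and 27 adjusted over the list alone. In the Treg signature 2 of 40 members were called lower and 24 adjusted over the list alone (median -1.14, camera adjusted p = 2.13e-17; adjusted p = 0.0534 with an estimated correlation). Coinhibitory receptors, among them Tigit and Pdcd1, had 2 of 14 members called lower and 4 adjusted over the list alone (median -0.56, camera adjusted p = 5.53e-06; adjusted p = 0.0693 with an estimated correlation). After scaling, the abundant members of these lists kept medians of -0.98, -0.84 and -0.89. These were the 3 lists called with an estimated correlation there (adjusted p = 0.0256, 0.00784 and 0.0256). Chemokine receptors and adhesion genes had 2 of 25 members called lower and 10 adjusted over the list alone (median -0.67, camera adjusted p = 5.86e-08; adjusted p = 0.105 with an estimated correlation).

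Lists for the processes in the series title were also called lower in unstimulated KO cells by camera with its preset correlation, and none with an estimated correlation. The DOCK8, actin and synapse machinery had a median of -0.55 over 43 members, 13 of them lower when adjusted over the list alone (camera adjusted p = 2.48e-10; adjusted p = 0.266 with an estimated correlation). Hcls1, a cortactin-like regulator of actin, was at 37.9 to 73.3 TPM in WT and 15.6 to 26.5 TPM in KO (limma adjusted p = 0.0719). Actr3, a subunit of the Arp2/3 complex, was at 156 ± 35.9 and 86.1 ± 31.9 TPM (limma adjusted p = 0.220). IL-2 STAT5 targets had a median of -0.51 over 53 members, 15 lower adjusted over the list alone (camera adjusted p = 1.93e-06; adjusted p = 0.136 with an estimated correlation). IL-2 receptor and JAK-STAT components had a median of -0.54 over 25 members, 7 lower adjusted over the list alone (camera adjusted p = 1.89e-06; adjusted p = 0.215 with an estimated correlation). Jak3, the kinase bound to the common gamma chain, was at 8.40 ± 2.55 and 3.64 ± 1.39 TPM (limma adjusted p = 0.214). After scaling, medians of the abundant members were -0.29 for the actin and synapse list, -0.52 for the STAT5 targets and -0.28 for the receptor components (camera adjusted p = 0.00129, 0.0169 and 0.0668). The T cell receptor and costimulation machinery had a median of -0.50 (camera adjusted p = 4.33e-06; adjusted p = 0.306 with an estimated correlation), with 6 of 30 members lower adjusted over the list alone. Genes induced by the receptor had a median of -0.31 (camera adjusted p = 0.0282; adjusted p = 0.379 with an estimated correlation), with Pdcd1 called among 39 members and 2 lower adjusted over the list alone.

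Metabolic and biosynthetic lists were lower too, in libraries whose scale factor was itself lower and where all abundant genes had a median of -0.44. Oxidative phosphorylation had a median of -0.82 over 43 members, 25 lower adjusted over the list alone (camera adjusted p = 7.53e-18; adjusted p = 0.0693 with an estimated correlation). Its abundant members had a scaled median of -0.46. Atp5c1 and Atp5a1, subunits of the mitochondrial ATP synthase, were at 101 ± 18.8 and 104 ± 33.1 TPM in WT and at 42.2 ± 24.4 and 48.5 ± 16.9 TPM in KO (limma adjusted p = 0.151 and 0.187). Glycolysis had a median of -0.90 over 23 members, 9 lower adjusted over the list alone (camera adjusted p = 4.62e-08; adjusted p = 0.0693 with an estimated correlation). The triose phosphate isomerase Tpi1 was at 30.1 ± 16.2 and 9.72 ± 4.08 TPM (limma adjusted p = 0.152). Medians were -0.54 for MYC targets and -0.59 for ribosomal proteins (camera adjusted p = 9.86e-07 and 2.35e-10; adjusted p = 0.129 and 0.379 with an estimated correlation). They were -0.47 for mTORC1 targets, -0.51 for the unfolded protein response and -0.44 for cholesterol synthesis (camera adjusted p = 0.00987, 0.000179 and 0.0392). With an estimated correlation these had adjusted p = 0.306, 0.306 and 0.290. Nop2, a nucleolar MYC target, was at 9.23 ± 3.20 TPM in WT and 1.99 ± 0.949 TPM in KO (limma adjusted p = 0.0596). Apoptosis and stress genes had medians of -0.43 and -0.47 (camera adjusted p = 0.0143 and 0.0439; adjusted p = 0.266 and 0.401 with an estimated correlation).

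Interferon-gamma, GBP and MHC genes had a median of -0.76 over 29 members, 12 lower adjusted over the list alone (camera adjusted p = 8.88e-10; adjusted p = 0.129 with an estimated correlation). Gbp7, a guanylate-binding protein, was at 18.4 ± 3.28 TPM in WT and 7.87 ± 1.88 TPM in KO. Psmb10, a subunit of the immunoproteasome, was at 23.7 ± 9.31 and 8.29 ± 3.17 TPM (limma adjusted p = 0.127 and 0.143). The naive and central T cell genes were not called, with a median of -0.13 as deposited and 0.12 in their abundant members when scaled (camera adjusted p = 0.667 and 0.397). Type I interferon genes (median -0.19), helper T cell genes (-0.31) and the G1/S (-0.09) and G2/M (-0.25) cell cycle lists were also not called. Among markers of other cells, only the stromal list was called, with a median of 0.30 over 14 members (camera adjusted p = 0.0447; adjusted p = 0.29 with an estimated correlation). CD8 T and NK cell markers had a median of -0.05, B cell genes 0.02, plasma cell genes -0.64, myeloid genes -0.25, neutrophil genes -0.01 and gamma delta T and innate lymphoid genes -0.46. Conventional T cell genes, with Id2 called, had a median of -0.33 (camera adjusted p from 0.112 to 0.998 for these lists).

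Calls between unstimulated genotypes depended on single libraries, with 5 genes called without WT library 1, 5 without KO library 1, 6 without KO library 2, 5 without KO library 4, 13 without the unnumbered WT library, 12 without WT library 2, 11 without WT library 3 and 67 without the unnumbered KO library. Tigit and Cxcr6 were called with any library left out. Pdcd1 lost its call without WT library 1 or 3 (limma adjusted p = 0.0547 and 0.0501), and Klrg1 without WT library 1 or KO library 1, 2 or 4 (0.0560 to 0.0639). The other genes named as called lost theirs without any 1 of at least 6 libraries, always including WT library 1 and KO libraries 1 and 2. When scaled, 8 of the 22 calls remained, 2 higher and 6 lower, among them Tigit, Pdcd1, Cxcr6, Klrg1 and Samt4.

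With beads, KO Treg cells had lower interferon-gamma, GBP and MHC genes than WT cells, and of the 37 lists this was the 1 list called by camera with either correlation. Its 29 members had a median log2 difference of -1.01 (camera adjusted p = 2.23e-31, and 0.0231 with an estimated correlation). Among all genes limma called 0 members, and 7 were lower adjusted over the list alone. Gbp10, an interferon-induced GTPase, was at 10.8, 6.70 and 5.28 TPM in WT and, in KO cells, at 1.15 TPM in library 4 and listed at 0 in library 5 (limma adjusted p = 0.448). Irgm1, an immunity-related GTPase, was at 49.8 ± 11.9 TPM in WT (SD, n = 3) and 12.7 ± 5.41 TPM in KO (n = 2; log2 -1.93, limma adjusted p = 0.590). Scaled to the abundant genes the list's abundant members had a median of -1.23, with 15 lower adjusted over the list alone (adjusted p = 0.00941 with an estimated correlation).

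**Figure D3:**
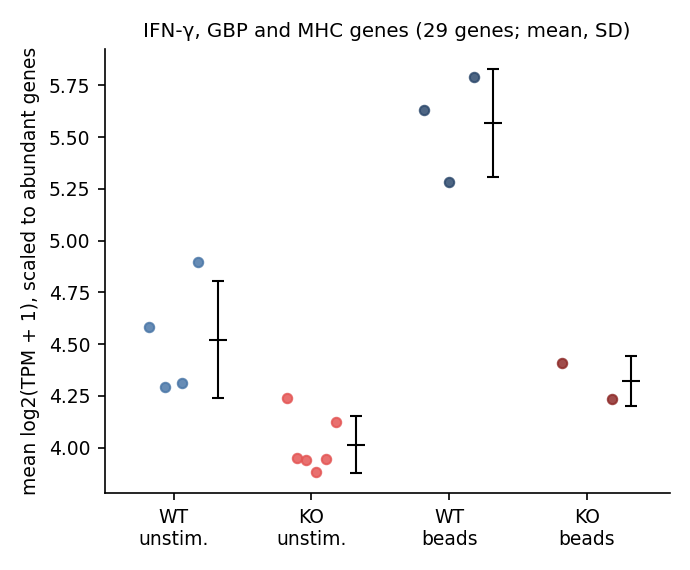
Mean log2(TPM + 1), scaled to abundant genes, of the 29 interferon-gamma, GBP and MHC genes (y axis) in each library of the 4 groups (x axis); points are libraries and bars are the mean with SD. With beads the WT libraries had 5.28 to 5.79 and the KO libraries 4.41 and 4.24, and without beads WT had 4.29 to 4.90 and KO 3.88 to 4.24.

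Only Apol7e, an apolipoprotein L family member, was called by limma between genotypes with beads (adjusted p = 0.0108). It was at 7.59, 9.47 and 6.39 TPM in WT and listed at 0 in both KO libraries. It was not called without WT bead library 1 (adjusted p = 0.0918) or KO bead library 4 or 5 (0.231 and 0.101), nor when scaled (0.171). The adjusted p over its alternatives ranged from 6.23e-06 to 0.743, and 3 genes were called without WT bead library 2. At an unadjusted p under 0.05 there were 868 genes, 652 higher and 216 lower in KO, fewer than the 1499 expected by chance. The fit shared the spread of a gene over all groups, while bead libraries correlated more closely than unstimulated ones (lowest r 0.874 and 0.706). The count may therefore be too low, and does not show that the genotypes were alike with beads. Tigit was at 197 to 263 TPM in WT and at 69.8 and 81.1 TPM in KO cells (log2 -1.56, SE 0.31, limma adjusted p = 0.505). Id2 was at 32.5 to 55.2 TPM in WT and at 7.89 and 12.2 TPM in KO (log2 -2.02, limma adjusted p = 1.00). Foxp3 was at 88.6 to 106 TPM in WT and at 42.2 and 42.7 TPM in KO (log2 -1.19, limma adjusted p = 1.00). Il2ra was at 190 ± 32.5 TPM in WT and 118 ± 30.1 TPM in KO (log2 -0.69) and Il2rb at 155 ± 11.7 and 126 ± 4.24 TPM. Ctla4 was at 186 ± 17.6 and 204 ± 9.41 TPM and Entpd1 at 130 ± 36.9 and 157 ± 10.2 TPM (limma adjusted p = 1.00 for these 4 genes). Batf, a transcription factor of effector Treg cells, was at 316 ± 94.4 and 83.5 ± 9.74 TPM, and the type 2 cytokine Il4 at 98.9 ± 58.5 and 5.56 ± 2.18 TPM (limma adjusted p = 1.00 for both). Of the 20 genes called lower in unstimulated KO cells, 9 had lower values in KO cells with beads, and of the 2 called higher, 0 had higher values. Over all genes tested, the genotype differences without and with beads had the same sign in 53.4%.

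camera called 16 of 37 lists between genotypes with beads, 15 lower and 1 higher in KO, none with a called member. fry called 0 of them. Effector Treg genes had a median of -0.62 with 5 members lower adjusted over the list alone (camera adjusted p = 4.88e-13; adjusted p = 0.132 with an estimated correlation). The Treg signature had a median of -0.40 with 1 (camera adjusted p = 8.21e-08, adjusted p = 0.142 with an estimated correlation, and 0.0446 in its abundant members when scaled). Helper T cell genes had a median of -0.26 with 3 members lower adjusted over the list alone (camera adjusted p = 0.000552; adjusted p = 0.182 with an estimated correlation). Type I interferon genes had a median of -0.20 with 2 (camera adjusted p = 0.00159; adjusted p = 0.324 with an estimated correlation). IL-2 STAT5 targets had a median of -0.21 with 1 (camera adjusted p = 0.000111; adjusted p = 0.281 with an estimated correlation). The list that was higher held naive and central T cell genes, with a median of 0.66 (camera adjusted p = 3.42e-06; adjusted p = 0.281 with an estimated correlation). Id3, an E protein inhibitor of resting T cells, was at 28.3 ± 5.36 TPM in WT and 102 ± 40.8 TPM in KO (limma adjusted p = 1.00). S1pr1, the receptor for exit from lymphoid organs, was at 13.7 ± 4.57 TPM and 27.3 TPM in both KO libraries. G1/S genes (median -0.42), MYC targets (-0.35) and oxidative phosphorylation (-0.29) were lower (camera adjusted p = 4.65e-07, 2.67e-06 and 2.67e-06). With an estimated correlation they had adjusted p = 0.132, 0.177 and 0.324. Ribosomal proteins (-0.26), stress genes (-0.31) and plasma cell genes (-0.76) were also lower (camera adjusted p = 6.16e-07, 0.00567 and 0.00233). With an estimated correlation they had adjusted p = 0.601, 0.350 and 0.132. G2/M genes, glycolysis and the unfolded protein response had medians of -0.28, -0.21 and -0.17 (camera adjusted p = 0.00136, 0.0424 and 0.0309). With an estimated correlation these had adjusted p = 0.364, 0.518 and 0.601. The DOCK8, actin and synapse machinery was not called, with a median of 0.04 and a test that pointed lower (camera adjusted p = 0.763). IL-2 receptor and JAK-STAT components (median -0.02) and the T cell receptor machinery (median 0.19) were not called either. Genes induced by the receptor and coinhibitory receptors, also not called, had medians of 0.14 and 0.15 and means of -0.03 and -0.05.

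Beads raised a T cell activation program in WT Treg cells. Il2ra rose by 4.00 on the log2 scale (SE 0.38, limma adjusted p = 6.16e-05), from 11.3 ± 3.90 to 190 ± 32.5 TPM (SD, n = 4 and 3). Irf4, a transcription factor of activated and effector Treg cells, rose by 5.53 (SE 0.38, limma adjusted p = 7.50e-06), from 1.14 ± 0.777 to 92.1 ± 1.90 TPM. Myc, a driver of growth, rose by 4.59, and the costimulatory receptors Tnfrsf4 (OX40) and Tnfrsf9 (4-1BB) by 3.61 and 3.79, Tnfrsf4 from 109 ± 41.4 to 1274 ± 10.2 TPM. The chemokine Ccl1 rose by 5.94 and the cytokines Tnf and Il4 by 4.76 and 5.27, with Tnf at 1.05 ± 0.778 TPM before and 52.5 ± 10.8 TPM after. Cish, a STAT5 target that restrains cytokine signalling, rose by 4.91 and Srm, which makes spermidine, by 4.94 (limma adjusted p from 6.16e-05 to 0.00203 for these genes). Timm8a1, a mitochondrial import chaperone listed at 0 in the 4 unstimulated WT libraries, was at 30.9 ± 15.2 TPM with beads (limma adjusted p = 0.000672). The histone gene Hist1h2ap was called at 331 to 821 TPM with beads (limma adjusted p = 0.0401), where 2 unstimulated libraries were listed at 0. Its call was lost without WT library 2 or 3 or any WT bead library (limma adjusted p from 0.0900 to 0.125, and from 0.0116 to 0.986 over all alternatives).

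Foxp3 rose with beads in WT cells by 1.20 (SE 0.37, limma adjusted p = 0.0479), from 43.2 to 98.7 TPM on average. The call was lost without any 1 of the 7 WT libraries (limma adjusted p from 0.0541 to 0.144). Il2rb rose by 1.59 (limma adjusted p = 0.0312), a call lost without any of them but WT library 3 (limma adjusted p from 0.0535 to 0.103). Ctla4 rose by 1.51 (limma adjusted p = 0.00842), while Entpd1 (-0.50) and Dock8 (-0.55) were not called (limma adjusted p = 0.307 and 0.295). In total limma called 3366 genes in WT cells, 1378 higher and 1988 lower. The largest falls among genes that the naming rule admits, which leaves out predicted genes and genes whose groups overlap, were in Tnnt1, a troponin subunit (53.5 to 136 TPM without beads and at most 23.5 TPM with beads, where 1 library was listed at 0), and in Khdrbs2, an RNA-binding protein (log2 -4.12, from 215 ± 78.8 to 27.9 ± 42.3 TPM). Other falls were in Nkain2 (-3.74), the potassium channel partner Kcnip2 (-3.70), Abhd15 (-3.42), the phospholipase Pla2g4a (-3.36) and the collagen Col4a1 (-3.30). The calls of Nkain2, Abhd15 and Col4a1 were lost without WT bead library 3 (limma adjusted p = 0.143, 0.0833 and 0.0607). Those of Nkain2 and Abhd15 were lost also without WT bead library 1 or 2 or WT library 2 or 3 (0.0504 to 0.153), with Nkain2 lost without WT library 1 as well (0.103). Among the fallen genes 50.4% had predicted or clone names, against 4.06% of those that rose. Il7r, the IL-7 receptor, fell from 58.8 ± 18.9 to 4.92 ± 1.15 TPM (limma adjusted p = 0.000172). S1pr1 fell from 74.3 ± 15.3 to 13.7 ± 4.57 TPM and Tcf7, which encodes TCF1, from 104 ± 46.6 to 17.4 ± 6.62 TPM (limma adjusted p = 0.000455 and 0.00119).

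camera called 21 of 37 lists for the bead response in WT cells, 20 higher and 1 lower, and 14 of them with an estimated correlation. Of 39 genes induced by the T cell receptor, 25 rose and 29 adjusted over the list alone (median 2.43, camera adjusted p = 2.28e-33). Of 44 MYC targets 36 rose and 38 adjusted over the list alone (median 2.65, camera adjusted p = 8.11e-50), among them the chaperonin Hspd1 (3.83) and the nucleolar Npm1 (3.01). Of 35 G1/S genes 28 rose and 31 adjusted over the list alone (median 2.16), such as the replication clamp Pcna (2.77) and the helicase subunit Mcm5 (3.53). Among 53 IL-2 STAT5 targets 23 rose and 3 fell, 25 and 3 adjusted over the list alone (median 1.20). In the Treg signature 21 of 40 rose and 1 fell, 23 and 1 adjusted over the list alone (median 1.40). Oxidative phosphorylation had 34 of 43 members higher and 39 adjusted over the list alone (median 1.94), and ribosomal proteins 46 of 49 and 48 (median 1.56). Glycolysis had 8 of 23 higher, with 12 higher and 1 lower adjusted over the list alone (median 1.05). Its member Ldha, lactate dehydrogenase, rose from 183 ± 60.1 to 1079 ± 90.5 TPM. mTORC1 targets (11 of 29, median 0.75), helper T cell genes (9 of 25 higher and 2 lower, median 0.79), stress genes (10 of 22 higher and 1 lower, median 1.43) and interferon-gamma, GBP and MHC genes (9 of 29, median 0.94) were higher as well. Adjusted over the list alone they had 13, 11, 11 and 13 members higher, and 0, 2, 1 and 0 lower. All lists named so far in this response held with an estimated correlation (adjusted p from 0.000412 to 0.0414).

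The lists that follow were called in WT cells, but not with an estimated correlation. Naive and central T cell genes were lower, with 11 of 30 members lower and 1 higher, 13 and 1 adjusted over the list alone (median -0.89, camera adjusted p = 0.000219; adjusted p = 0.252 with an estimated correlation). Effector Treg genes had 9 of 40 higher and 2 lower, 12 and 2 adjusted over the list alone (median 0.24, camera adjusted p = 1.18e-05; adjusted p = 0.211 with an estimated correlation). The cytokine Il10 (3.69) and the chemokine receptor Ccr8 (4.64) were among those that rose. The DOCK8, actin and synapse machinery had 4 of 43 higher and 4 lower, 5 and 4 adjusted over the list alone (median 0.33, camera adjusted p = 0.000219; adjusted p = 0.436 with an estimated correlation). Profilin, Pfn1, and cofilin, Cfl1, rose by 1.79 and 1.62. IL-2 receptor and JAK-STAT components had 11 of 25 higher and 4 lower, 11 and 6 adjusted over the list alone (median 0.41, camera adjusted p = 0.000219; adjusted p = 0.246 with an estimated correlation). Coinhibitory receptors had 5 of 14 higher and 2 lower (median 0.02, camera adjusted p = 0.0208; adjusted p = 0.244 with an estimated correlation). G2/M and apoptosis genes had medians of 0.59 and 0.39 (camera adjusted p = 2.12e-07 and 0.000219; adjusted p = 0.0782 and 0.0552 with an estimated correlation). The count of called genes fell to 1736, 1861 and 1650 without WT bead library 1, 2 or 3 and to 2242 without WT library 2. The split of 1378 higher and 1988 lower became 1877 and 1347 under median-ratio scaling, 1200 and 898 under quantile normalization, 1488 and 1291 without ribosomal genes and 1113 and 3249 without the repeat-derived genes. Bead libraries carried less repeat-derived signal, by -13.8 percentage points in WT (exact permutation p = 0.0571, n = 3 and 4) and -21.0 in KO cells (exact permutation p = 0.0357, n = 2 and 6). With the level of genes that T cells do not use as a covariate, limma called 0 genes in WT cells and 41 in KO cells, against 3366 and 2431 without it. All WT bead libraries lay below all unstimulated WT libraries in this covariate, and the median SE of a gene rose from 0.507 to 0.947 in WT and from 0.542 to 0.851 in KO cells. Folds of Il2ra, Irf4, Myc and Tnfrsf9 stayed large while their SE grew. In WT they went from 4.00 (SE 0.38) to 3.43 (SE 0.71) for Il2ra and from 5.53 (SE 0.38) to 5.35 (SE 0.73) for Irf4 (limma adjusted p = 0.156 and 0.0555 with the covariate). This does not hold for every gene that rose, since Hist1h2ap changed sign in WT with the covariate.

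KO Treg cells also raised an activation program with beads. Il2ra rose by 3.35 (SE 0.40, limma adjusted p = 0.000205), from 11.2 ± 4.43 to 118 ± 30.1 TPM (SD, n = 6 and 2). Irf4 rose by 5.16, from 1.33 ± 0.694 to 79.7 ± 9.35 TPM, and Myc by 4.88, from 4.24 ± 2.22 to 143 ± 21.5 TPM (limma adjusted p = 2.26e-05 and 4.23e-05). Tnfrsf4 rose by 4.90 and Tnfrsf18 by 3.65, from 50.9 ± 21.8 to 1421 ± 91.2 and from 52.8 ± 15.7 to 651 ± 64.5 TPM (limma adjusted p = 2.71e-05 and 3.63e-05). Nr4a1, an immediate reporter of T cell receptor signals, rose by 4.97, the chemokine receptor Ccr8 by 5.54, Nme1, a nucleoside diphosphate kinase, by 5.70 and the chemokine Ccl20 by 5.32 (limma adjusted p from 0.000124 to 0.000895). Lsm7, an RNA-processing protein listed at 0 in the 6 unstimulated KO libraries, was at 57.1 and 65.9 TPM with beads (limma adjusted p = 0.00238). Pdcd1 rose by 2.63 in KO cells (limma adjusted p = 0.00773), from 6.98 ± 5.24 to 40.8 ± 1.06 TPM, and was at 63.7 ± 26.4 and 35.8 ± 2.23 TPM in WT (log2 -0.71, limma adjusted p = 0.408). The difference between these responses, 3.34, was not called (adjusted p = 0.581). Foxp3 rose by 1.72 (limma adjusted p = 0.0137), to 42.5 ± 0.386 TPM, Il2rb by 2.51 (0.00440) and Ctla4 by 2.93 (0.000201). Entpd1 (-0.50) and Dock8 (-0.28) were not called (limma adjusted p = 0.404 and 0.699).

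limma called 2431 genes for the bead response in KO cells, 1785 higher and 646 lower. The falls named by rule were in Pla2g4a (-4.13), Tnnt1 (-4.01), Ctrcos (-3.52), Ptpro, a receptor-type phosphatase (-3.11), Tex14 (limma adjusted p = 0.0170) and in Tex43, Hand2os1 and Apol7e, the latter 3 listed at 0 in both KO bead libraries. Il7r fell by 1.74, from 29.5 ± 12.4 to 7.57 ± 0.372 TPM (limma adjusted p = 0.0157), and Ly6c1, a surface marker of resting lymphocytes, by 2.52 (limma adjusted p = 0.0122). camera called 24 of 37 lists, 23 higher and 1 lower, and 15 with an estimated correlation. Genes induced by the T cell receptor had 29 of 39 members higher and 32 adjusted over the list alone (median 2.63), MYC targets 36 of 44 and 39 (median 2.94) and G1/S genes 23 of 35 and 28 (median 1.95). Oxidative phosphorylation had 39 of 43 higher and 40 adjusted over the list alone (median 2.49), ribosomal proteins 44 of 49 and 49 (median 1.93) and glycolysis 11 of 23 and 13 (median 1.58). IL-2 STAT5 targets had 26 of 53 higher, 30 higher and 1 lower adjusted over the list alone (median 1.72). The Treg signature had 25 of 40 higher and 1 lower by either adjustment (median 2.34). These lists, together with mTORC1 targets (9 of 29, median 1.42), helper T cell genes (7 of 25, median 0.79), coinhibitory receptors (6 of 14, median 1.06), apoptosis genes (5 of 29, median 0.53) and stress genes (10 of 22, median 1.10), held with an estimated correlation (adjusted p from 0.000734 to 0.0470). Adjusted over the list alone the last 5 had 14, 9, 6, 6 and 10 members higher and 1, 0, 1, 0 and 0 lower.

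Effector Treg genes had 12 of 40 members higher in KO cells with beads and 13 adjusted over the list alone (median 0.96, camera adjusted p = 6.32e-09; adjusted p = 0.0851 with an estimated correlation). The DOCK8, actin and synapse machinery had 15 of 43 higher, 19 higher and 1 lower adjusted over the list alone (median 0.91, camera adjusted p = 5.57e-11; adjusted p = 0.167 with an estimated correlation). Pfn1 rose by 2.65, Cfl1 by 2.36 and Hcls1 by 1.78. IL-2 receptor and JAK-STAT components had 10 of 25 higher and 1 lower, 11 and 2 adjusted over the list alone (median 0.47, camera adjusted p = 6.92e-07; adjusted p = 0.116 with an estimated correlation). The T cell receptor machinery had 8 of 30 higher and 1 lower, 14 and 1 adjusted over the list alone (median 0.81, camera adjusted p = 1.44e-06; adjusted p = 0.211 with an estimated correlation). Interferon-gamma, GBP and MHC genes had 4 of 29 higher by either adjustment (median 0.65, camera adjusted p = 6.60e-05; adjusted p = 0.211 with an estimated correlation). Hypoxia, p53 and G2/M genes had medians of 0.36, 0.42 and 0.63 (camera adjusted p = 0.0222, 0.0429 and 0.000501; adjusted p = 0.172, 0.209 and 0.211 with an estimated correlation). Stromal genes were the list that was lower (median -0.63, camera adjusted p = 0.0285; adjusted p = 0.172 with an estimated correlation). The count of called genes was 614 without KO bead library 4 and 380 without KO bead library 5, where the lone KO bead library was assumed to vary like the other groups. Without either, calls were lost for Foxp3 (limma adjusted p = 0.131 and 0.155), Il2rb (0.0693 and 0.0778), Il7r (0.131 and 0.173), Ly6c1, Pla2g4a, Tnnt1, Tex43, Hand2os1, Ptpro and Tex14. They were lost without KO bead library 5 for Lsm7 (0.0512), Hcls1 (0.0512) and Ctrcos (0.606), whose log2 change was -1.04 there. The split of 1785 higher and 646 lower became 1731 and 1136 under median-ratio scaling, 1362 and 877 under quantile normalization, 2005 and 284 without ribosomal genes, 1247 and 1883 when scaled to abundant genes and 1338 and 1739 without the repeat-derived genes.

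The bead responses of WT and KO cells, which share no library, shared more called genes than independent lists would. Across 29989 genes, which are not independent replicates, their log2 changes had a Pearson r of 0.618 and a Spearman rho of 0.522. Both responses called 1141 genes higher, of 1378 in WT and 1785 in KO cells, against 82.0 for independent lists. Both called 440 lower, of 1988 and 646, against 42.8. There was 1 gene called in opposite directions. Abundant genes made up 88.5% and 88.6% of the genes called higher in WT and KO cells, against 14.4% and 14.5% of genes not called. Among abundant genes alone, when scaled, 1321 were called higher in both, against 448 for independent lists, and 907 lower, against 254. Il2ra, Irf4, Myc, Tnfrsf9, Tnf and Hspd1 rose in both, and Il7r fell in both. Il4 rose in WT cells and had a log2 change of 0.91 in KO cells (limma adjusted p = 0.636). The difference between responses was -4.37 (SE 1.30) with an adjusted p of 0.999. The genotype differences without and with beads had a Pearson r of 0.0860 and a Spearman rho of 0.122 across genes. In these comparisons 0 genes were called in both, where the lists held 22 and 1.

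**Figure D4:**
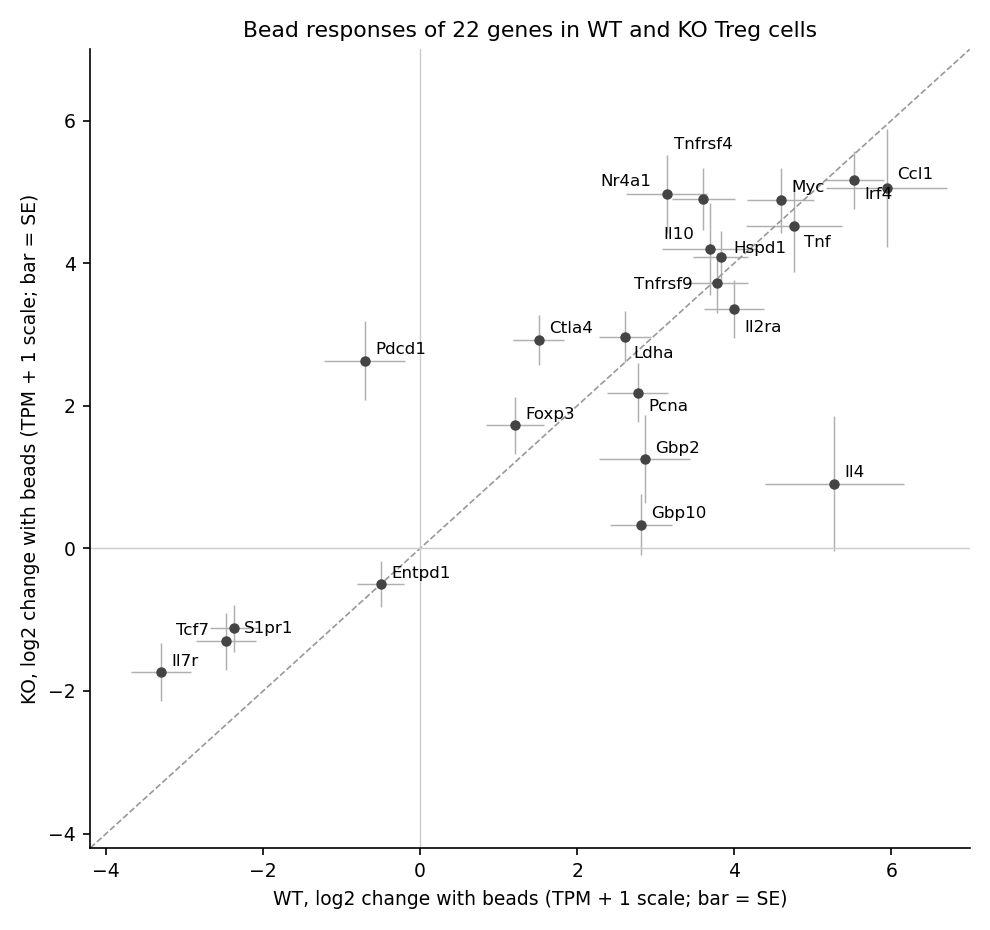
Log2 change of 22 genes with beads in WT (x axis) and KO Treg cells (y axis), on the log2(TPM + 1) scale; points are genes, bars are SE and the dashed line marks equal change. Il2ra rose by 4.00 and 3.35, and Il4 changed by 5.27 in WT and 0.91 in KO cells, a difference that was not called.

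The test of the difference between bead responses called 1 of 29989 genes, ENSMUSG00000096252, which carries no symbol here and was singled out after its values were seen (log2 4.33, SE 0.56, limma adjusted p = 0.0356). The test called 0 genes when scaled to abundant genes, with quantile normalization or with a pseudocount of 5. The gene was listed at 0 in the 6 unstimulated KO libraries and at 13.9 and 13.4 TPM in the KO bead libraries. It was at 5.04, 11.2, 8.37 and 15.2 TPM in unstimulated WT and 6.93, 4.04 and 9.64 TPM in WT bead libraries. An unadjusted p under 0.05 was reached by 1247 genes, fewer than the 1499 expected by chance. Of the genes named throughout, Foxp3 (0.52), Il2ra (-0.65), Il2rb (0.92), Ctla4 (1.42), Entpd1 (0.00) and Dock8 (0.27) had limma adjusted p of 0.9986 or more. Simulated changes of 2 on the log2 scale were called in 2.99% of genes by this test, with the same spread drawn for all groups. Differences of that size could therefore mostly have been missed here, though the share may differ where the spread is unequal. camera called 12 of 37 lists, 10 with a higher and 2 with a lower log2 change with beads in KO cells than in WT cells, while 0 were called with an estimated correlation or by fry. Of the 10, naive and central T cell genes and chemokine receptors and adhesion genes had negative medians with beads, -0.89 and -0.79 in WT and -0.40 and -0.24 in KO cells, so their medians fell less in KO. The gene count of this test was 0 to 6 with 1 library left out, with 6 called without WT library 3.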

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

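The tests of the repeat-derived genes, of scaling to abundant genes, of conventional T cell genes and of CD8 and NK markers were chosen only after the results they weigh were seen, while the tests of relabelled libraries and of differences between responses were chosen before.

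A library far from the others of its group was found in 4 of 100 tests, each of a library measure or a named gene in unstimulated WT or KO libraries. At 1 in 20, 5 are expected by chance. This is a rough guide, since tests share libraries and some genes were picked because their groups did not overlap. Bead libraries were not examined in this way. KO library 2 had 415 abundant genes listed at 0, against 174 to 264 in the other unstimulated KO libraries, a gap of 0.627 of the range. The unnumbered KO library had Ctla4 at 51.6 TPM, against 19.9 to 25.4 TPM (0.747 of the range), and Klrg1 at 0.978 TPM where the other 5 were listed at 0 (gap of 1, the whole range). KO library 5 had Ptpn4 at 3.06 TPM, against 0.680 to 1.27 TPM (0.658 of the range).

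A difference between bead responses was called for ENSMUSG00000096252, of 4.33 on the log2 scale (SE 0.56, limma adjusted p = 0.0356), where 0 genes were called when scaled to abundant genes, with quantile normalization or with a pseudocount of 5. camera called 12 lists, with adjusted p from 2.14e-05 to 0.0355, while 0 were called with an estimated correlation (adjusted p from 0.703 to 0.835) or by fry. Their medians stand beside 0.27 for all genes and 0.47 for abundant genes. Medians were 0.61 for the Treg signature, 0.69 for IL-2 receptor and JAK-STAT components, 0.74 for T cell receptor machinery, 0.66 for the DOCK8, actin and synapse machinery, 0.75 for naive and central T cell genes, 0.50 for effector Treg genes and 0.44 for coinhibitory receptors. Glycolysis had 0.64, oxidative phosphorylation 0.52 and chemokine receptors and adhesion genes 0.82, while interferon-gamma, GBP and MHC genes had -0.0673 and G1/S genes -0.24.

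Some genes listed for 1 set of libraries alone, and so outside every comparison, had at least 5 TPM in each library of that set. In bead libraries these were Gm9761 (mean 254 TPM), Gm4459 (112), Gm13509 (29.8), Mir5136 (29.3), Gm14017 (24.6), Gm23766 (17.6), Gm20689 (16.2), Trav10d (16.0), Ndufa11b (15.1) and Rps2-ps10 (13.2). In unstimulated libraries it was Igkv4-72 (22.9).

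The 22 genes called between unstimulated genotypes were weighed against chance and against lower TPM of abundant genes in KO libraries. Of 100 assignments of the 10 libraries out of 210, counting the labelled one, 3 called at least 22 genes, and the highest other count was 373, from an exchange of WT library 2 with the unnumbered KO library; for the bead response in WT cells 1 of 35 assignments, the labelled one, reached 3366 genes, and the next called 124. Leaving out the repeat-derived genes, abundant genes kept a median of -0.304 in KO (-0.443 as deposited; -0.382 to -0.250 with 1 library left out), which argues against those genes as the whole cause. Within genotypes the abundant genes' median had a slope of -0.0958 on the level of genes that T cells do not use (permutation p = 0.726, 100000 resamples), which leaves a background spread over the genome open. Dock8 was at 9.15 TPM in WT library 2, the lowest of the WT libraries, and at 11.9 TPM in the unnumbered KO library, the highest of the KO libraries. Tigit (176 and 53.8 TPM), Cxcr6 (37.7 and 2.75 TPM), Ptpn4 (27.6 and 1.05 TPM) and Acot7 (31.7 and 8.54 TPM) followed the labels, but were named because they differ between the labelled groups, so an exchange of these labels stays open.

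The lower effector Treg genes of unstimulated KO cells kept a median of -0.983 in 26 abundant members when scaled (-1.27 as deposited; -1.16 to -0.897 with 1 library left out), and 25 of the 26 were lower, which argues against dilution of all genes by background. Conventional T cell genes had a scaled median of 0.0101 (quartiles -0.333 to 0.431), with 8 of 16 lower, which leaves open whether activated conventional T cells in the YFP-negative sort contributed. DOCK8 deficiency is the biological explanation in the design, and YFP, Cre and the X chromosome in use go with it in every library.

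The lower interferon-gamma, GBP and MHC genes of KO cells with beads had a scaled median of -1.10 (-1.01 as deposited; -1.17 to -1.01 with 1 library left out), with 28 of 29 lower, which argues against dilution. CD8 and NK cell markers had a scaled median of 0.312 (0.127 to 0.348 with 1 library left out), with 6 of 19 lower and a lower quartile of -0.352, which leaves such cells in the WT libraries open. A CD3+ sort would remove NK cells and a CD4+ sort CD8 T cells, and the sources name each in a different place. Among markers singled out after their values were seen, Nkg7 was at 29.6 TPM in WT and 9.48 TPM in KO and Ifng at 2.32 and 0.948 TPM, with a lower mean in KO for Gzmb too. Cd8b1 was at 4.97 ± 1.99 TPM in WT (SD, n = 3) and 7.15 ± 1.82 TPM in KO (n = 2). Cd8a, Prf1 and Klrd1, near the floor, were at 0.994 ± 0.546, 0.674 ± 0.0362 and 1.08 ± 0.689 TPM in WT. In KO they were at 2.29 ± 0.135, 1.39 ± 0.595 and 3.46 ± 4.89 TPM, so the KO libraries were far apart for Klrd1. WT and KO bead libraries carry different numbers; unstimulated KO libraries 4 and 5 differed from 1, 2 and 3 by 0.110 in the list's mean, but residual correlations of 0.00994 and -0.00728 between same-numbered KO libraries gave no sign that a number marks an animal, so a difference between animals remains open.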

How the results depend on the processing

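The tests with abundant genes, repeat-derived genes, the background covariate and without 4 KO libraries were added after the results were seen. Of 5708 values of named genes under alternatives, 5270 kept their side of the threshold, 35 of them uncalled with a change of sign, 414 lost a call, 23 gained 1 and 1 reversed: Hist1h2ap with beads in WT, at -0.54 with the background covariate (limma adjusted p = 0.986). The causes of the moves below were not tested, apart from smaller numbers of genes or samples. TPM keep no depth, so limits set by depth could not be measured.

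KO against WT without beads, 22 genes, gave 8 with a pseudocount of 0.1 and 13 with 5, 6 with median-ratio scaling, 6 with quantile normalization, 4 with only the groups compared, 5 with array weights, 44 without the unnumbered libraries, 8 scaled to abundant genes, 10 without repeat-derived genes, 46 with abundant genes only, 4 with both, 6 with the covariate, 11 without the 4 KO libraries, and 5 to 67 with 1 library left out. Its 20 lists became 0 with an estimated correlation, 12 with abundant genes only, 10 with scaling as well and 11 without the 4 KO libraries (14 to 21 with 1 library left out).

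KO against WT with beads, 1 gene, gave 2 and 0 with pseudocounts of 0.1 and 5, 15 with only the groups compared, 19 with array weights, 2 without the unnumbered libraries, 0 scaled to abundant genes, 0 with abundant genes only, 0 with both and 0 to 3 with 1 library left out. Its 16 lists became 1 with an estimated correlation and 0 with fry (12 to 16 with 1 library left out).

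Beads in WT, 3366 genes, gave 2098 with quantile normalization, 6042 with array weights, 0 with the covariate and 1650 to 3380 with 1 library left out (21 to 23 lists, 21 in the main test). Beads in KO, 2431 genes, gave 1198 with only the groups compared, 3961 with array weights, 41 with the covariate, 995 without the 4 KO libraries and 380 to 2703 with 1 library left out. Its 24 lists became 15 with an estimated correlation (21 to 24 with 1 library left out).

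The difference between responses, 1 gene, gave 3 and 0 with pseudocounts of 0.1 and 5, 2 with the stricter filter, 0 with quantile normalization, 2 without ribosomal genes, 5 with array weights, 5 without the unnumbered libraries, 0 scaled, 2 without repeat-derived genes, 0 with abundant genes only, 0 with both, 2 with the covariate, 4 without the 4 KO libraries and 0 to 6 with 1 library left out. Its 12 lists became 0 with an estimated correlation, 0 with fry, 7 with median-ratio scaling and 4 without the 4 KO libraries (9 to 14 with 1 library left out). Only the groups compared was not run here, since this test needs all 15 libraries.

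The r of 0.618 between bead responses was 0.391 and 0.751 with pseudocounts of 0.1 and 5, 0.675 with the stricter filter, 0.558 with quantile normalization, 0.590 without ribosomal genes, 0.569 without repeat-derived genes, 0.775 with abundant genes only, 0.776 with both, 0.724 with the covariate and 0.539 to 0.627 with 1 library left out. The r of 0.0860 between genotype differences was 0.0476 and 0.129 with these pseudocounts, 0.107 with the stricter filter, 0.0983 with median-ratio scaling, 0.0671 with quantile normalization, 0.0687 without the unnumbered libraries, 0.0738 without repeat-derived genes, 0.155 with abundant genes only, 0.156 with both, 0.146 with the covariate and 0.0548 to 0.0931 with 1 library left out.

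The Dock8 difference without beads (-0.67) was -0.40 with median-ratio scaling (exact permutation p = 0.0810) and -0.49 with quantile normalization (exact permutation p = 0.0810). It was -0.31 scaled to abundant genes (exact permutation p = 0.138) and -0.85 to -0.46 with 1 library left out. Without the 4 KO libraries it was -0.49 (exact permutation p = 0.333), where the libraries left are too few for a p under 0.05. With beads (-0.39) the difference was -0.59 to -0.20 with 1 library left out.

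Libraries with the same title number had residual correlations between -0.0249 and 0.0265, and not every library correlated best with its own number, so the numbers gave no sign of pairing. With so few libraries, low residual correlations do not rule out that WT and KO libraries with the same number share a mouse. With the number as a block, calls between genotypes were 1 gene without beads, and with beads 0 genes and 7 lists; the bead response in KO had 922 genes, and the difference between responses 0 genes and 7 lists. With the block the r of bead responses was 0.541 and that of genotype differences 0.423. No number has bead libraries of both genotypes, so the blocked genotype difference with beads runs through unstimulated KO libraries. Both genotype differences then share libraries, which by itself can raise their r. Dock8 had -0.76 with the block (exact permutation p = 0.5, n = 3 pairs). These pairs are too few for a p under 0.05 in that test.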

Other observations

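Nothing in this part rests on tests chosen only after the result was seen, except the comparison of scalings for relabelled libraries and the description of called genes by level.

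Beads also raised lists for protein folding and sterol synthesis. Of 25 unfolded protein response genes 13 rose and 1 fell in WT cells, 16 and 1 adjusted over the list alone (median 1.41, camera adjusted p = 7.39e-14, and 0.0335 with an estimated correlation), and 15 rose in KO cells, 16 adjusted over the list alone (median 1.86, camera adjusted p = 6.53e-14, and 0.0361 with an estimated correlation). Hspa5, the chaperone BiP of the endoplasmic reticulum, rose by 2.97 in WT and 3.22 in KO, and Sec61b, a subunit of the translocation channel, by 2.33 in WT (limma adjusted p = 0.000117, 9.35e-05 and 0.000709). Of 30 cholesterol synthesis genes 5 rose in WT and 9 in KO cells, 11 and 17 adjusted over the list alone (medians 1.03 and 1.26, adjusted p = 0.00565 and 0.00583 with an estimated correlation). Idi1, an isomerase of the pathway, rose by 2.03 in WT (limma adjusted p = 0.00194) and 1.82 in KO, and Hmgcs1, an early enzyme, by 1.77 in WT (limma adjusted p = 0.00576) and 1.93 in KO; both KO calls were lost without KO bead library 4 or 5.

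Type I interferon genes moved apart with beads in WT cells, with 3 of 41 higher and 7 lower, 3 and 8 adjusted over the list alone, and no call for the list (median -0.60, camera adjusted p = 0.663). Ddx58, the RNA sensor RIG-I, fell from 171 to 39.2 TPM on average (limma adjusted p = 0.000924), while Bst2, which tethers virus particles, rose by 2.77 and Ifi35 by 1.44 (limma adjusted p = 0.00218 and 0.00753). In KO cells Ddx58 had a change of -0.92 (limma adjusted p = 0.119), and the difference between responses, 1.25, was not called (adjusted p = 0.999). Chemokine receptors and adhesion genes were not called as a list in WT cells, with 4 of 25 higher and 5 lower, 4 and 9 adjusted over the list alone (median -0.79, camera adjusted p = 0.46). Ccr8 rose by 4.64 and Itga4, an integrin chain for entry into tissue, fell by 2.05 (limma adjusted p = 0.00193 and 0.000426).

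Genes that rose and genes that fell with beads differed in level. The median of mean TPM was 35.1 for the 1378 genes that rose in WT cells and 11.8 for the 1988 that fell, and 35.1 and 16.6 for the 1785 and 646 in KO cells. Predicted or clone names made up 50.4% of the genes that fell in WT and 61.9% of those that fell in KO, against 36.6% and 37.4% of genes not called. Of 1211 tested receptor, keratin-associated and defensin genes, 13 were called in WT and 9 in KO cells, all lower.

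The exchange of WT library 2 with the unnumbered KO library called 373 genes as deposited, 322 of them lower, 233 when scaled to abundant genes, 21 of them lower, 50 after quantile normalization, 32 of them lower, and 1 with median-ratio scaling, and shared 1 gene with the 22 of the labelled groups as deposited. An assignment that set KO libraries 1, 2, 4 and 5 apart called 206 genes as deposited and 2 when scaled to abundant genes.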
